A study of Homo sapiens with 14 samples.

How the data were processed

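Gene expression was measured on 14 one-colour arrays hybridised with RNA from WM9, an established human melanoma cell line. Per the labels, 12 of the arrays held cells kept in 10 µM PLX4720, an inhibitor of the BRAF kinase, for 12, 24, 48, 60, 72 or 96 h, and the remaining pair held cells kept in the solvent DMSO for 96 h. Each of the 7 groups thus had 2 arrays, which the series' design text describes as biological replicates, and each array was assigned to its group and replicate number from its own label.

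Per the labels' protocols, total RNA was extracted with a phenol-based reagent and turned into biotin-labelled cRNA for Illumina arrays. The scanner, the summarising software and its settings are not given in the sources used here. The deposited unnormalized table held, per the file headers and the values, 1 signal intensity per probe and array on a linear scale for 47322 probes, all above 0 and at different levels on different arrays. Its 28 further columns were empty, so detection p-values, bead counts and negative control probes were not used here. The deposited normalized table held log2 values that had been quantile normalized by the authors: the sorted values of the 14 arrays differed by at most 0.01, each array had a median of 8.41, and probes kept the rank order of the signals to within 0.01. The distribution to which those log2 values were fitted by the authors and the software used for that step are not given in the sources used here.

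All results were computed from the unnormalized signals. The design fixed before the data were examined called for the neqc method of limma, which needs detection p-values or negative controls. In its place, signals were corrected with limma's normexp model fitted by the saddle-point method with an offset of 16, converted to log2 and quantile normalized. A probe was counted as above background on an array when its signal exceeded the mode of that array's signals by more than the 1% upper tail of a normal distribution with the spread of the signals below the mode. Between 17787 and 19363 probes per array (37.6% to 40.9%) were above background by this measure, and median raw signals ranged from 232 to 370. The DMSO arrays had the highest medians, 366 and 370, against 232 to 316 on the PLX4720 arrays. A probe had to exceed 411 and 427 on the DMSO arrays, and 264 to 352 on the PLX4720 arrays, to count as above background. Background level and treatment thus cannot be told apart in comparisons with DMSO. The number of arrays limits the precision of every value.

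Probe names came from a table of the platform's annotation: 30113 probes had 1 gene, 8 had several and 17201 were not named there. Of the named probes, 30074 were matched by gene identifier to the symbols of RefSeq for GRCh38.p14. The names covered 20046 genes. For each gene the brightest probe among those above background on at least 2 arrays was used, which left 12749 genes from 17086 named probes. Where probes of a gene above background on at least 2 arrays pointed in different directions, this is stated beside the gene. BRAF and DCT, which were to be reported whatever their result, and messenger RNAs of the mitochondrial genome were not analysed here.

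Log2 values were fitted gene by gene with lmFit and eBayes of limma 3.58.1 in R 4.3.3, over all 7 groups, with 7 residual degrees of freedom and 5.87 prior degrees of freedom. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method within each comparison at 0.05. Standard errors (SE) are those of the log2 fold change in this fit. A gene not above background on either array of a group has only a bound there: the fold was computed against the higher of the dim probe's own value and the lowest value above background, and is written as at least that size. Each PLX4720 time was compared with DMSO, 96 h with 12 h, and each time with the one before it, and an F test asked which genes differed among the 6 PLX4720 times. Of the 37 gene lists fixed before the data were examined, 36 had at least 3 tested genes and were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. With an estimated correlation the lists called fell from 7 to 5 at 12 h against DMSO, from 19 to 7 at 96 h against DMSO and from 14 to 6 at 96 h against 12 h. The fry test, which asks whether a list's genes move one way on balance without comparing them with other genes, called 16, 31 and 29.

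The genes named were fixed by a rule: for the 3 comparisons 12 h against DMSO, 96 h against DMSO and 96 h against 12 h, the 6 largest rises and the 6 largest falls past the threshold with all arrays of a group beyond those of the other, the 2 largest rises and the 2 largest falls within each list, and a fixed set of ERK, mitochondrial, pigment, cell cycle and glucose genes whatever their result. Any other gene named is marked as chosen after its values were seen.

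Replicate numbers were checked for pairing. Deviations from the group means of same-numbered arrays correlated with r = 0.15 to 0.42 over the 15 pairs of PLX4720 groups, and with r = -0.2 to 0.42 over the 6 pairs of DMSO with a PLX4720 group. The numbers were therefore treated as possible pairs among the PLX4720 groups, and not between DMSO and PLX4720. The fit of the 12 treated arrays with the replicate number as a block is given where it moves a count by over 1.5 times. Standard errors and p-values come from the fit without the block unless the block is named. Replicate 2 had the lower median raw signal in every PLX4720 group, but not in DMSO. A shared difference in signal level thus cannot be told apart from paired cultures.

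The fit was tested on simulated data for the comparison of 96 h with DMSO, over 12749 genes and 20 simulations. With an even spread and 200 altered genes, 4.7% of calls were false. With the spread measured in each group the share rose to 28.6%, because the DMSO arrays varied more than the others, and it was 4.9% with limma's array weights. With 4000 altered genes the shares were 11% and 3.4%. Noise was drawn separately for each gene here too, so a difference between the DMSO arrays common to many genes was not simulated. The shares, those with array weights included, therefore give no error rate for such a difference. At the measured spread 14.5% of genes altered 1.5-fold, 53.1% of genes altered 2-fold and 93.2% of genes altered 4-fold were recovered, against 1.2%, 23.6% and 82.4% with array weights.

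Alternatives chosen in advance were the deposited normalized values, no background correction, an offset of 50, median scaling in place of quantile normalization, no filter on dim probes, probes above background on all 14 arrays, the mean of a gene's probes, a trended and robust variance, array weights, a fit of only the groups compared, the replicate number as a block, an estimated inter-gene correlation, fry, and leaving out each array in turn. Added after seeing the data were normexp with the background taken from the mode of each array, the array's score on the leading axis within groups as a covariate, and fits of the 12 treated arrays with and without the replicate block. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.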

Results

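The series title concerns what BRAF inhibition does to oxidative phosphorylation and senescence in melanoma. WM9 melanoma cells were treated with 10 µM PLX4720, a BRAF inhibitor, and transcript levels of 12749 genes were compared with those of cells kept in DMSO for 96 h. There were 14 arrays, 2 in each of the 7 groups, with PLX4720 at 12, 24, 48, 60, 72 and 96 h. The only control was taken at 96 h, so the comparisons at 12 to 72 h hold hours in culture together with the drug. The DMSO arrays differed from each other more than the arrays of any treated group: the standard deviation across genes of the difference between the replicates was 0.559 on the log2 scale for DMSO, with 6.98% of genes over 2-fold apart, and 0.301 to 0.347 for the PLX4720 groups.

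With both DMSO arrays, the number of genes that differed from DMSO was larger at later times. By limma at an adjusted p of 0.05 it was 2198 at 12 h (1146 higher and 1052 lower), 2652 at 24 h (1466 and 1186), 3198 at 48 h (1774 and 1424), 3214 at 60 h (1796 and 1418), 3537 at 72 h (1924 and 1613) and 3816 at 96 h (2097 and 1719). With array weights, which allow the spread to differ between arrays, the counts were 854, 1197, 1529, 1609, 1930 and 1896. The median log2 fold change over all genes stayed at 0.06 at 12 h and 0.07 at 96 h. With 2 arrays a group these weights acted on the standard errors and left the fold changes as they were. Median scaling aligned the medians of all 47322 probes, of which 37.6% to 40.9% per array were above background. Probes at background level thus set this scaling. It moved the median over all genes at 96 h from 0.07 to -0.27 and at 12 h from 0.06 to -0.14. The split was then 387 higher and 1361 lower at 12 h, 550 and 1603 at 24 h, 761 and 1962 at 48 h, 647 and 2327 at 60 h, 763 and 2400 at 72 h, and 751 and 2883 at 96 h. Quantile normalization gives all arrays 1 distribution, which holds the median over all genes near 0. Neither split thus shows which direction prevailed among expressed genes. The counts also rested on single arrays: without replicate 1 or 2 of the treated group they were 1306 and 1128 at 12 h, 1653 and 1241 at 24 h, 1946 and 2103 at 48 h, and 2275 and 2058 at 72 h. At 60 h the count without replicate 2 was 1938 and at 96 h the count without replicate 1 was 2521. The order of the times rested on which DMSO array was kept: the counts at 12, 24, 48, 60, 72 and 96 h were 2849, 3179, 4299, 3698, 4478 and 3373 without DMSO replicate 1, and 2604, 3109, 2718, 3417, 3021 and 4733 without DMSO replicate 2.

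**Figure D1:**
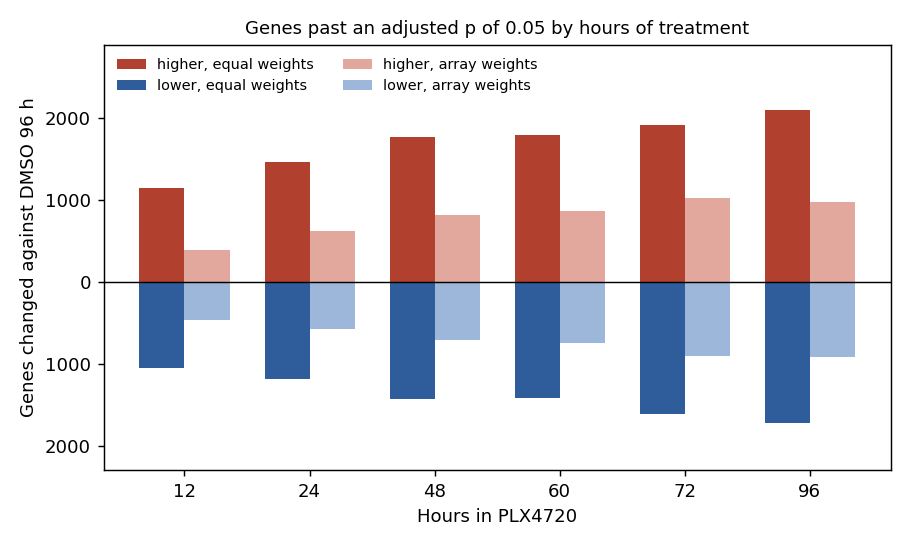
Number of genes higher (up) or lower (down) than DMSO at a limma adjusted p of 0.05, by hours in PLX4720, with equal weights (dark bars) and with array weights (light bars). The total goes from 2198 at 12 h to 3816 at 96 h with equal weights, and from 854 to 1896 with array weights.

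The comparison of 12 h with DMSO addresses the early effect of the inhibitor. Genes driven by ERK, the kinase downstream of BRAF, were far lower at 12 h. SPRY4, a feedback inhibitor of receptor signalling, was 56.9-fold lower (log2 fold change -5.83, SE 0.27, limma adjusted p = 4.83e-08; n = 2 arrays a group here and below). The ERK-induced transcription factor ETV5 was 31.3-fold lower (SE 0.17 on the log2 scale) and DUSP6, a phosphatase that acts on ERK, 15.7-fold lower (SE 0.19). CCND1, which encodes cyclin D1, was 11.8-fold lower (SE 0.17) and MYC 10.1-fold lower (SE 0.17). SPRY1 was not above background at 12 h and was at least 21.4-fold lower, SPRY2 was 19.2-fold lower and TIMP3, an inhibitor of matrix metalloproteinases, 16.7-fold lower. Of 20 tested genes of ERK output, 19 fell and 1 did not pass, with 19 also falling when adjusted over the list alone. The list's median was -1.72 (camera adjusted p = 2.04e-23). SPRY4 was above background on 1 of the 2 arrays of 12 h.

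Cholesterol synthesis and uptake genes fell as well: 15 of 17 fell, 2 did not pass and 16 fell adjusted over the list alone. The median was -2.17 (camera adjusted p = 1.04e-19). CYP51A1, a demethylase of the sterol pathway, was 9.75-fold lower (SE 0.27) and HMGCS1, which makes HMG-CoA, 9.45-fold lower (SE 0.30). Genes of the ATF4 amino acid and stress response rose in 17 of 21 cases with none falling and 4 not passing, and 17 also rose adjusted over the list alone. Their median was 1.32 (camera adjusted p = 1.73e-13). SLC7A11, the cystine transporter, was 6.45-fold higher (SE 0.18) and PSAT1, an enzyme of serine synthesis, 3.82-fold higher (SE 0.17). Outside the lists, the largest rises were in HMOX1, heme oxygenase 1, at 13.1-fold (log2 fold change 3.71, SE 0.22, limma adjusted p = 3.45e-07), ID3, an inhibitor of differentiation factors, at 9.66-fold, GCLM, a subunit of the enzyme that starts glutathione synthesis, at 9.32-fold, and ID1, of the same family as ID3, at 8.92-fold. The crystallin gene CRYGS and the aldo-keto reductase gene AKR1B10 were not above background in DMSO and were at least 13.4-fold and at least 5.84-fold higher.

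Genes that peak in G2 and mitosis were higher at 12 h than in the 96 h control. Of 51 tested, 31 rose, 1 fell and 19 did not pass (36 rose and 1 fell adjusted over the list alone), with a median of 0.95 (camera adjusted p = 5.48e-15). HMMR was 3.42-fold higher (SE 0.22) and CDCA2 3.18-fold higher (SE 0.25). The proliferation marker MKI67, above background on 1 of the 2 DMSO arrays, was 1.86-fold higher at a limma adjusted p of 0.043. That adjusted p became 0.226 with array weights and 0.09 with median scaling, and the call was lost under 14 of the alternatives. Genes of G1/S had no common direction: of 39 tested, 5 rose, 2 fell and 32 did not pass, with the same counts adjusted over the list alone and a median of 0.11 (camera adjusted p = 0.453), TK1 being 2.83-fold higher and CDCA7 2.34-fold lower. LMNB1, the lamin B1 gene whose loss is used as a senescence marker, had a log2 fold change of 0.47 (SE 0.20, limma adjusted p = 0.139).

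Interferon-stimulated genes rose in 11 of 25 cases, 1 fell and 13 did not pass (12 and 1 adjusted over the list alone), at a median of 0.59 (camera adjusted p = 0.000219). IFI44L, above background on 1 of the 2 DMSO arrays, was 6.94-fold higher (SE 0.32) and IFI27, not above background in DMSO, at least 2.92-fold higher, whereas BST2 was 3.03-fold lower with a limma adjusted p of 0.00395, or 0.0586 with array weights. Leukocyte markers had 2 of 4 rising, as also adjusted over the list alone, at a median of 0.38 (camera adjusted p = 0.314). These were CD2 at 1.61-fold (limma adjusted p = 0.0114, 0.0932 with array weights) and LYZ at 1.9-fold (0.0142 and 0.11), the latter above background on 1 of the 2 DMSO arrays. The medians of fibroblast, keratinocyte and endothelial markers were -0.10, 0.27 and -0.19, none of these lists being called. The list of CDK inhibitors and senescence genes shifted down at a median of -0.30 (camera adjusted p = 0.0112, and adjusted p = 0.0889 with an estimated correlation), with 2 members rising, 5 falling and 9 not passing, as also when adjusted over the list alone. The risers were CDK inhibitors, CDKN1C at 3.51-fold (SE 0.23, above background on 1 of the 2 DMSO arrays) and CDKN1B at 1.85-fold (limma adjusted p = 0.00911, 0.0904 with array weights), the latter with only 1 of its 2 probes in this direction. The members that fell were the G1 cyclin gene CCND1, the insulin-like growth factor binding protein genes IGFBP5 (6.53-fold) and IGFBP7, the growth factor gene GDF15 (3.96-fold) and the caveolin gene CAV1. Of these, CAV1 and IGFBP7 were named after their values were seen. CDKN1A, which encodes p21, had a measured log2 fold change of -0.30 (SE 0.16, limma adjusted p = 0.224; 0.13 with median scaling). Its raw signals lay near the top of the scale, so the size of any difference in its transcript was not determined at this or later times. CDKN2A had one of -0.16 (SE 0.35, adjusted p = 0.804; 0.19 without DMSO replicate 2). Chaperones of the endoplasmic reticulum had a median of -0.26, with 0 rising, 2 falling and 13 not passing and the same counts adjusted over the list alone (camera adjusted p = 0.0189, and adjusted p = 0.0889 with an estimated correlation). Without DMSO replicate 1 that adjusted p was 0.28 and without 12 h replicate 1 it was 0.0639.

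Respiratory chain genes, the subject of the title, hardly differed at 12 h: 3 of 71 rose, none fell and none passed adjusted over the list alone, at a median of 0.16 (camera adjusted p = 0.231). PPARGC1A, the coactivator that drives mitochondrial biogenesis, was 1.86-fold higher (log2 fold change 0.89, SE 0.25, limma adjusted p = 0.0288), and cytochrome c, CYCS, was 2-fold higher (SE 0.23, adjusted p = 0.00904). With array weights the adjusted p values were 0.0996 and 0.0728. The TFAM log2 fold change, 12 h against DMSO, was 0.94 (SE 0.30, adjusted p = 0.0481). That call, of a gene whose protein binds mitochondrial DNA, was lost under 19 of the alternatives, those without single arrays included, with an adjusted p of 0.166 with array weights and 0.211 with median scaling, and the value was 0.41 (adjusted p = 0.293) without DMSO replicate 2 and 1.47 without DMSO replicate 1. Of 15 pigment lineage genes, 0 rose, 4 fell and 11 did not pass, as also adjusted over the list alone, at a median of -0.24 (camera adjusted p = 0.157). TYRP1, an enzyme of melanin synthesis, was 4.43-fold lower (SE 0.22). MITF, the melanocyte lineage factor, had a log2 fold change of -0.27 (SE 0.26, adjusted p = 0.544), which was 0.23 without DMSO replicate 1 and 0.09 as the mean of its 2 probes. TYR and MLANA were above background in neither group. Among glycolysis genes 2 rose and 4 fell out of 21, as also adjusted over the list alone, with a median of 0.21 and a camera direction of down (adjusted p = 0.949). The glucose transporter genes SLC2A1 and SLC2A3 went apart, 2.65-fold higher (SE 0.25) and 3.16-fold lower (SE 0.17). Of 23 secreted factors of senescent cells, 1 rose (MMP3, 2.19-fold) and 6 fell, among them CXCL8 by 6.32-fold (SE 0.29) and PLAT by 2.97-fold (SE 0.19). Adjusted over the list alone 2 rose and 6 fell, with a median of -0.06 (camera adjusted p = 0.169). In the BCL2 family, 2 of 15 rose and 3 fell (5 and 5 adjusted over the list alone), at a median of 0.05 and a camera direction of down (adjusted p = 0.949). The pro-apoptotic BMF was 2.86-fold higher (SE 0.18) and the pro-apoptotic PMAIP1 2.65-fold lower (SE 0.23). BCL2L11, not above background in DMSO, did not pass (adjusted p = 0.0862). The hexokinase gene HK2 was 1.59-fold higher (adjusted p = 0.0124, 0.101 with array weights), with only 1 of its 2 probes in this direction. ERBB3 and AXL had log2 fold changes of -0.19 (adjusted p = 0.525) and 0.27 (adjusted p = 0.519). That of AXL was -0.08 with median scaling and that of ERBB3 0.17 as the mean of its 3 probes.

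The comparison of 96 h with DMSO, the only one with a control of the same hours, addresses the state of the cells late in treatment. Cell division genes were lower. Of 51 G2/M genes 45 fell, 1 rose and 5 did not pass (47 fell and 1 rose adjusted over the list alone), at a median of -1.61 (camera adjusted p = 4.41e-24). The mitotic kinase genes NEK2 and BUB1 were 10.8-fold lower (SE 0.28) and 6.59-fold lower (SE 0.29), both above background on 1 of the 2 arrays of 96 h. Of 39 G1/S genes 26 fell, 1 rose and 12 did not pass (29 and 1 adjusted over the list alone), at a median of -0.98 (camera adjusted p = 3.88e-12). The exonuclease gene EXO1 was 7.08-fold lower (SE 0.19) and the replication licensing factor gene CDT1 6.52-fold lower (SE 0.24). LMNB1 was 4.05-fold lower (log2 fold change -2.02, SE 0.20, limma adjusted p = 1.13e-05), and MKI67, not above background at 96 h and above it on 1 of the 2 DMSO arrays, did not pass (adjusted p = 0.107).

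ERK output stayed low at 96 h: 16 of 20 genes fell, 1 rose and 3 did not pass, with the same 16 and 1 adjusted over the list alone, at a median of -1.10 (camera adjusted p = 1.34e-11). SPRY4 was 38.8-fold lower (SE 0.27), ETV5 13.8-fold (SE 0.17), DUSP6 8.03-fold (SE 0.19), CCND1 7.05-fold (SE 0.17) and MYC 2.4-fold lower (SE 0.17). The gene that rose, MAFF, was 1.61-fold higher (adjusted p = 0.0356, 0.139 with array weights). Of the sterol genes 16 of 17 fell and 1 did not pass, as also adjusted over the list alone, at a median of -2.48 (camera adjusted p = 6.69e-16). MSMO1 was 22-fold lower (SE 0.19, 2 of its 3 probes in this direction) and HMGCS1 17.9-fold lower (SE 0.30). The other large falls were in VIPR1, a receptor for vasoactive intestinal peptide, at 23.4-fold (SE 0.24), the imprinted growth regulator PHLDA2 at 20-fold (SE 0.28) and the protease inhibitor gene SERPINA3 at 17.9-fold (SE 0.23), the last 2 above background on 1 of the 2 arrays of 96 h.

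Respiratory chain genes were higher at 96 h. Of 71 nuclear-encoded subunits 34 rose, none fell and 37 did not pass (39 rose adjusted over the list alone), at a median of 0.53 (camera adjusted p = 3.49e-08, and adjusted p = 0.122 with an estimated correlation). Cytochrome c, CYCS, was 5.74-fold higher (log2 fold change 2.52, SE 0.23, limma adjusted p = 4.21e-06), and the complex I subunits NDUFB1 and NDUFA6 were 2.72-fold (SE 0.28) and 2.7-fold higher (SE 0.20). PPARGC1A was 6.45-fold higher (log2 fold change 2.69, SE 0.25, limma adjusted p = 6.36e-06) and the nuclear receptor gene ESRRA, its partner on respiratory promoters, 3.45-fold higher (SE 0.21). With median scaling the list's median was 0.09, against -0.27 for all genes. Between the 2 DMSO arrays themselves the list's median differed by 0.23. By complex, 18 of 34 genes of complex I rose, as also adjusted over the list alone, at a median of 0.55 (camera adjusted p = 4.29e-05, and adjusted p = 0.174 with an estimated correlation). Complexes II and III with cytochrome c had 6 of 12 rising, as also adjusted over the list alone, at a median of 0.61 (camera adjusted p = 0.00136). SDHA was 2.13-fold higher (SE 0.23, adjusted p = 0.00313, 0.116 with median scaling). Complex IV had 7 of 10 rising, and all 10 adjusted over the list alone, at a median of 0.56 (camera adjusted p = 0.00211, and adjusted p = 0.144 with an estimated correlation). COX6A1 was 2.15-fold higher (SE 0.18). For complex V 3 of 15 rose, as also adjusted over the list alone, at a median of 0.37 (camera adjusted p = 0.0372, and adjusted p = 0.148 with an estimated correlation). With median scaling that median was -0.125, and the adjusted p was 0.156 without DMSO replicate 1 and 0.0835 without 96 h replicate 1.

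**Figure D2:**
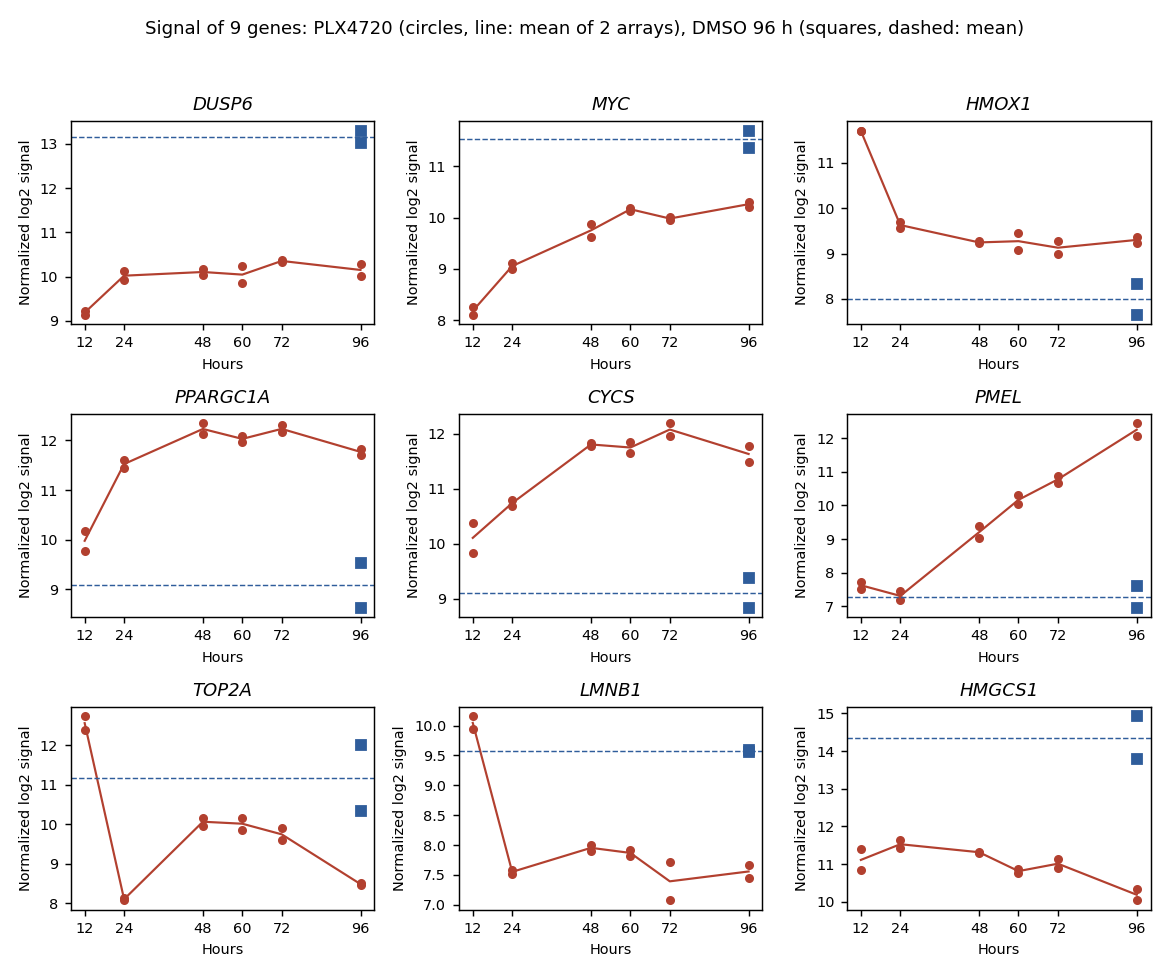
Normalized log2 signal of 9 genes by hours in PLX4720 (red circles, 1 per array, the line joining the means of 2 arrays) and in DMSO at 96 h (blue squares, the dashed line their mean). Both 12 h arrays of HMOX1 and TOP2A lie above both DMSO arrays, while at 96 h PPARGC1A, CYCS and PMEL lie above and DUSP6, MYC, TOP2A, LMNB1 and HMGCS1 below both DMSO arrays.

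Other metabolic lists were mixed. Of 18 genes of fatty acid oxidation 9 rose, 1 fell and 8 did not pass (9 and 2 adjusted over the list alone), at a median of 0.60 (camera adjusted p = 0.00764, and adjusted p = 0.122 with an estimated correlation). ACADS was 3.06-fold higher (SE 0.19), ETFDH 2.28-fold higher (SE 0.16) and ECI2 1.95-fold lower (SE 0.18). In the tricarboxylic acid cycle 8 of 19 rose and 1 fell (9 and 1 adjusted over the list alone), at a median of 0.49 (camera adjusted p = 0.0372, and adjusted p = 0.119 with an estimated correlation). IDH3A was 3.15-fold higher (SE 0.17). The call of this list was also lost with median scaling (median 0.12, adjusted p = 0.101), without DMSO replicate 2 (adjusted p = 0.163) and without 96 h replicate 1 (adjusted p = 0.0835). Regulators of mitochondrial biogenesis had no common direction, with 3 of 19 rising and 1 falling (2 and 1 adjusted over the list alone) at a median of 0.10 (camera adjusted p = 0.787, the median -0.31 with median scaling). TFB1M was 2.71-fold lower (SE 0.19). TFAM had a log2 fold change of 0.20 (SE 0.30, adjusted p = 0.657) that was -0.22 with median scaling and -0.33 without DMSO replicate 2. Of 54 mitochondrial ribosomal protein genes 6 rose and 2 fell (2 and 0 adjusted over the list alone), at a median of 0.18 (camera adjusted p = 0.253, the median -0.25 with median scaling). MRPL34 was 2.59-fold higher (SE 0.18). Of 21 glycolysis genes 6 rose and 3 fell (7 and 3 adjusted over the list alone), at a median of 0.30 (camera adjusted p = 0.337). The median log2 fold change of the list glycolysis, 96 h against DMSO, was 0.179 without DMSO replicate 1, 0.472 without DMSO replicate 2 and 0.04 with median scaling. HK2, the hexokinase, was 3.49-fold higher (SE 0.16), and GAPDH was 2.55-fold lower (SE 0.20). SLC2A1 had a log2 fold change of 0.15 (SE 0.25, adjusted p = 0.686) that was -0.29 with median scaling and -0.17 without DMSO replicate 1.

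Genes of lysosomes and of the pigment lineage were higher. Of 34 lysosomal genes 23 rose, 1 fell and 10 did not pass (24 and 1 adjusted over the list alone), at a median of 0.81 (camera adjusted p = 5.94e-09). The glucosidase gene GAA was 5.05-fold higher (SE 0.24) and the cathepsin gene CTSK 4.88-fold higher (SE 0.15). Of 21 autophagy genes 7 rose and 14 did not pass (9 rose adjusted over the list alone), at a median of 0.47 (camera adjusted p = 0.00825, and adjusted p = 0.0579 with an estimated correlation). With median scaling the median was 0.01 at an adjusted p of 0.101. WIPI1 was 2.15-fold higher (SE 0.18, adjusted p = 0.000616, 0.0586 with median scaling). Of 15 pigment lineage genes 10 rose and 5 did not pass (11 rose and 1 fell adjusted over the list alone), at a median of 0.84 (camera adjusted p = 3.21e-05). PMEL, the fibril protein of pigment granules, was 31.1-fold higher (log2 fold change 4.96, SE 0.24, limma adjusted p = 3.56e-08), APOE 5.58-fold higher (SE 0.19) and MLANA, not above background in DMSO, at least 1.47-fold higher. The probe of TYR was above background in neither group, and MITF had a log2 fold change of 0.68 (SE 0.26, adjusted p = 0.0706). The largest rises of all were in LGI3, a secreted neuronal protein, at least 43.9-fold, and in CRYAB, the small heat shock protein alpha B-crystallin, at 41.4-fold (SE 0.25). RAP1GAP, which switches off the GTPase RAP1, rose 25.6-fold (SE 0.20), the secretory pathway gene DIPK1C 23.5-fold (SE 0.23) and the sorting receptor gene SORCS2 at least 13.3-fold. PMEL and DIPK1C were above background on 1 of the 2 DMSO arrays.

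Senescence-related lists went in mixed directions at 96 h. The list of CDK inhibitors and senescence genes had 3 members rising, 7 falling and 6 not passing, as also adjusted over the list alone, at a median of -0.33 (camera adjusted p = 0.0485, and adjusted p = 0.141 with an estimated correlation). The call was lost in 10 of the 14 fits that left out a single array, with an adjusted p of 0.152 without DMSO replicate 2 (median -0.145), 0.0638 without 96 h replicate 2, and from 0.0507 without 60 h replicate 2 to 0.057 without 24 h replicate 2 in the other 8. Among the CDK inhibitors, CDKN1B was 1.91-fold higher (adjusted p = 0.00394, 0.146 with median scaling, with 1 of its 2 probes in this direction). CDKN2A was 3.07-fold lower (SE 0.35, adjusted p = 0.00376, 0.052 with array weights). The measured signal of CDKN1A, near the top of the scale, was lower by an amount not determined (adjusted p = 0.0171, 0.109 with array weights and 0.373 with median scaling). The transcriptional repressor gene BHLHE40 was 2.22-fold higher (SE 0.15), and of 2 insulin-like growth factor binding proteins IGFBP3 was 2.87-fold higher (SE 0.22) and IGFBP5 5.15-fold lower (SE 0.19). Of 23 secreted factors of senescent cells 10 rose, 7 fell and 6 did not pass (12 and 7 adjusted over the list alone), at a median of 0.67 (camera adjusted p = 0.463). The median was 0.401 without 96 h replicate 2. The cytokine genes IL6 and CCL2 were 9.78-fold (SE 0.21) and 5.89-fold higher (SE 0.17) and the collagenase gene MMP1 5.05-fold lower (SE 0.23). Of 21 p53 targets 2 rose and 3 fell (1 and 3 adjusted over the list alone), at a median of -0.05 (camera adjusted p = 0.699, the median 0.126 without DMSO replicate 2). SESN1 was 1.8-fold lower (SE 0.17). In the BCL2 family 4 of 15 rose and 1 fell (6 and 2 adjusted over the list alone), at a median of 0.22 (camera adjusted p = 0.39, the median -0.101 with median scaling). The pro-apoptotic BMF was 7.45-fold higher (SE 0.18) and PMAIP1 3.27-fold lower (SE 0.23). BCL2L11 was not above background in either group.

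Stress and immune lists followed. ATF4 response genes rose in 13 of 21 cases, 1 fell and 7 did not pass (14 and 1 adjusted over the list alone), at a median of 0.83 (camera adjusted p = 0.000115, and adjusted p = 0.0542 with an estimated correlation). The transcription factor genes ATF3 and DDIT3 were 6.62-fold (SE 0.18) and 3.44-fold higher (SE 0.17), and SLC7A11 1.47-fold lower (adjusted p = 0.034, 0.175 with array weights). Of 18 genes of antigen presentation 10 rose and 8 did not pass (12 rose adjusted over the list alone), at a median of 0.62 (camera adjusted p = 0.000565, and adjusted p = 0.149 with an estimated correlation). The peptide transporter gene TAP2 was 3.45-fold higher (SE 0.20). This list's median also differed by 0.31 between the DMSO arrays. Interferon-stimulated genes were split, 5 rising, 11 falling and 9 not passing, as also adjusted over the list alone, at a median of -0.43 (camera adjusted p = 0.0485, and adjusted p = 0.144 with an estimated correlation). BST2 and ISG15 were 7.39-fold (SE 0.32) and 5.06-fold lower (SE 0.32), and MX2 2.11-fold higher (adjusted p = 0.00106, 0.0582 with median scaling). BST2 and ISG15 were above background on 1 of the 2 arrays of 96 h. Among probes above background on all 14 arrays this median was 0.056 (adjusted p = 0.637), without DMSO replicate 2 the adjusted p was 0.189 and without 96 h replicate 1 it was 0.0772. For chaperones of the endoplasmic reticulum 5 of 15 fell and 1 rose, as also adjusted over the list alone, at a median of -0.49 (camera adjusted p = 0.0198, adjusted p = 0.0928 with an estimated correlation and 0.0943 without DMSO replicate 1). PDIA4 was 2.03-fold lower (adjusted p = 0.014, 0.0953 with array weights). Heat shock genes had a median of -0.01, with 1 of 11 falling and 0 adjusted over the list alone (camera adjusted p = 0.39, the median 0.05 without DMSO replicate 2).

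The remaining lists were not called at 96 h. Genes of the invasive melanoma state split into 4 rising and 5 falling of 13, as also adjusted over the list alone, at a median of -0.04 (camera adjusted p = 0.463). NGFR, a neural crest receptor, and THBS1, a matrix glycoprotein, were 6.49-fold (SE 0.30) and 5.18-fold higher (SE 0.20), and CCN2, a matrix factor, was 8.69-fold lower (SE 0.16). AXL was 1.79-fold lower (SE 0.25, adjusted p = 0.0251, 0.166 with array weights), and ERBB3 had a log2 fold change of 0.00 (adjusted p = 0.996), with 1 of its 3 probes in the direction of the brightest. Receptor tyrosine kinases and insulin receptor substrates had 1 of 12 rising and 5 falling, as also adjusted over the list alone, at a median of -0.04 (camera adjusted p = 0.228, the median 0.03 without DMSO replicate 2). EPHA2 was 2.22-fold lower (SE 0.20) and PDGFRB, not above background at 96 h, at least 1.52-fold lower. Of 20 hypoxia genes 6 rose and 3 fell (8 and 3 adjusted over the list alone), at a median of 0.08 (camera adjusted p = 0.463, the median -0.305 with median scaling). LOX, which crosslinks collagen, was 4.09-fold lower (SE 0.19). Cytosolic ribosomal proteins had 5 of 48 rising and 5 falling (3 and 5 adjusted over the list alone) at a median of -0.05 (camera adjusted p = 0.39). Ribosome biogenesis factors had 1 of 27 rising and 3 falling (0 and 1 adjusted over the list alone), at a median of 0.11 but a mean of -0.04 and a camera direction of down (adjusted p = 0.668, the median -0.35 with median scaling). Of 9 reference genes 1 rose and 2 fell, as also adjusted over the list alone, GAPDH among the latter, at a median of -0.17 (camera adjusted p = 0.315, the median 0.08 without DMSO replicate 2). Markers of other cell types were few: fibroblast markers had 1 of 6 rising and 1 falling at a median of -0.04 (camera adjusted p = 0.787, the median 0.08 without 96 h replicate 1), and leukocyte markers 1 of 4 rising at a median of 0.37 (adjusted p = 0.39, the median -0.03 without the filter on dim probes). Keratinocyte markers had 2 of 3 falling at a median of -1.37 (adjusted p = 0.12), which was 0.02 without the filter on dim probes. That median was the value of KRT14, whose probe was above background in neither group. Endothelial markers had 0 of 3 passing at a median of 0.21 (adjusted p = 0.877, the median -0.05 without DMSO replicate 2).

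**Figure D3:**
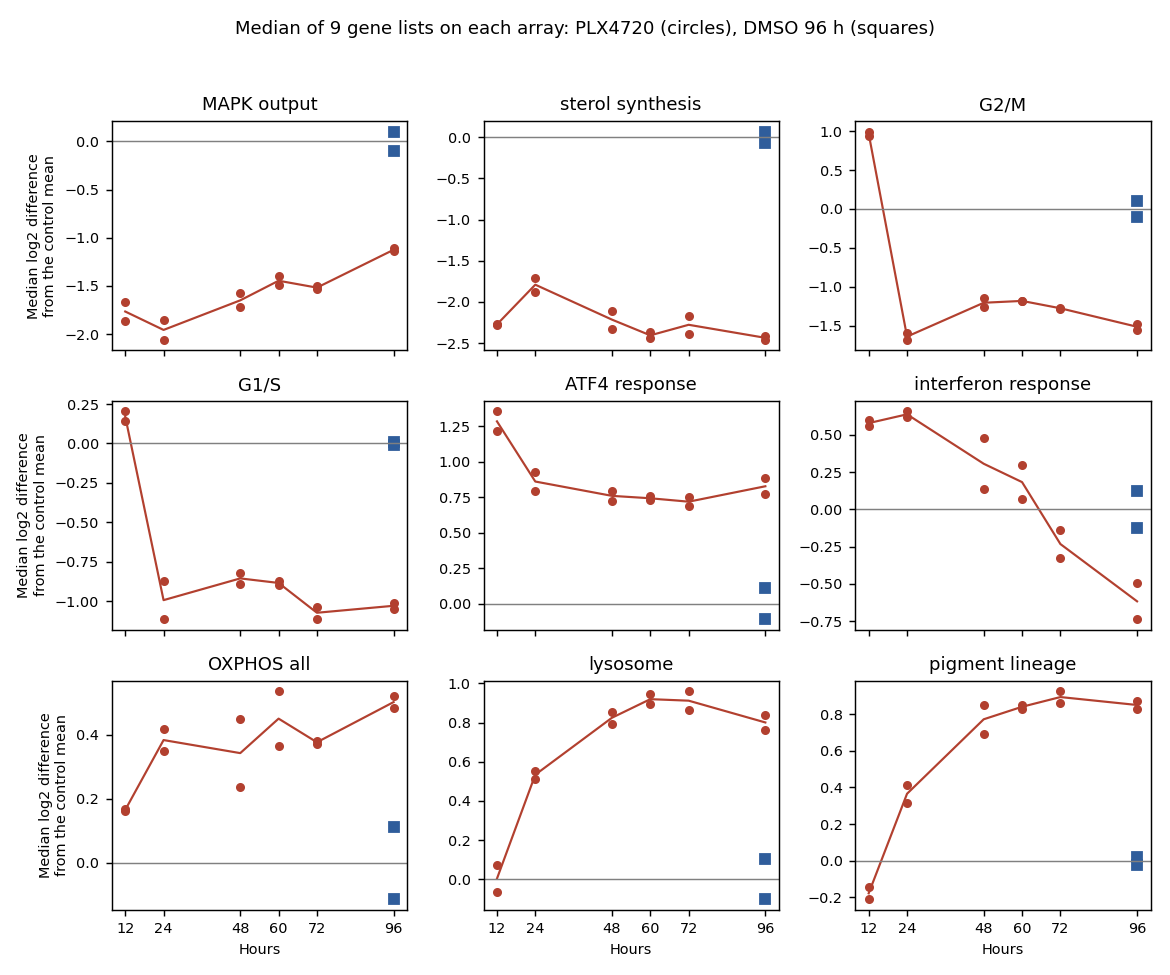
Median log2 difference from the DMSO mean over the genes of 9 lists, on each PLX4720 array by hours (red circles, the line joining the means of 2 arrays) and on each DMSO array at 96 h (blue squares). G2/M genes lie near 0.95 above DMSO at 12 h and below it from 24 h on, and lysosome and pigment lineage genes lie near DMSO at 12 h and above it from 24 h on.

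The comparison of 96 h with 12 h, within the treated cells, in which the DMSO arrays enter only the spread, asks how the response developed, with hours in culture as part of it. It called 3700 genes, 1919 higher and 1781 lower at 96 h. Genes of cell division fell further than any other list: 49 of 51 G2/M genes fell and 2 did not pass, as also adjusted over the list alone, at a median of -2.38 (camera adjusted p = 2.77e-36). In G1/S, 26 of 39 genes fell (28 fell and 1 rose adjusted over the list alone), at a median of -1.17 (camera adjusted p = 1.87e-12). TOP2A, the mitotic topoisomerase, was 16.8-fold lower (SE 0.38), BUB1 15.1-fold (SE 0.29), TK1 11.8-fold (SE 0.29), LMNB1 5.61-fold (SE 0.20), and NCAPG, a condensin gene not above background at 96 h, at least 13.5-fold lower. Outside these lists ID1 was at least 15.5-fold lower, the ADP-ribosyltransferase gene ART3 21.1-fold lower (SE 0.33), HKDC1, related to hexokinases, 17.4-fold lower (SE 0.23) and the mitotic kinase gene PBK 15.5-fold lower (SE 0.31). ID1 was not above background at 96 h. Interferon-stimulated genes fell in 16 of 25 cases and rose in 2, as also adjusted over the list alone, at a median of -1.03 (camera adjusted p = 8.15e-07). ISG15 and IFI44L were 13.1-fold (SE 0.32) and 10.6-fold lower (SE 0.32). At 96 h BUB1, HKDC1, PBK, ISG15 and IFI44L were above background on 1 of the 2 arrays.

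Pigment lineage genes rose from 12 h to 96 h in 11 of 15 cases with 1 falling (12 and 1 adjusted over the list alone), at a median of 0.94 (camera adjusted p = 5.27e-07). PMEL was 24.6-fold higher (SE 0.24) and TYRP1 11.8-fold higher (SE 0.22). Lysosomal genes rose in 18 of 34 cases (20 adjusted over the list alone), at a median of 0.65 (camera adjusted p = 8.11e-08). The cathepsin genes CTSK and CTSF were 6.17-fold higher (SE 0.15) and 5.53-fold higher (SE 0.19). ERK output regained part of its level, 11 of 20 genes rising and none falling (12 and 1 adjusted over the list alone), at a median of 0.68 (camera adjusted p = 0.00119). The list's median change from 72 h to 96 h was 0.32. Across genes that step ran parallel to the difference between the DMSO arrays, which was 0.20 for this list. MAFF was 5.77-fold higher (SE 0.23), MYC 4.22-fold higher (SE 0.17), and SPRY4 at a log2 fold change of 0.56 (SE 0.27, adjusted p = 0.142). The largest rises were in LGI3, at least 44.3-fold, CRYAB at 57.5-fold (SE 0.25), SORCS2 at least 13.4-fold, ANGPTL7 at 29.8-fold (SE 0.16) and the neuronal pentraxin gene NPTX1 at 21.7-fold (SE 0.17). PPARGC1A was 3.47-fold higher at 96 h than at 12 h (SE 0.25) and HK2 2.2-fold higher (SE 0.16). Of the other genes fixed before the data were examined, ETV5 (log2 fold change 1.18, adjusted p = 0.000166), DUSP6 (0.96, 0.00192), CCND1 (0.74, 0.00513) and MITF (0.94, 0.0165) were higher. With median scaling the adjusted p values of the last 3 were 0.0846, 0.0622 and 0.175. MLANA, not above background at 12 h, was at least 1.49-fold higher and MKI67, not above background at 96 h, at least 1.8-fold lower. SLC2A1 (-1.25, adjusted p = 0.00212) and AXL (-1.11, 0.00527) were lower, whereas TFAM (-0.74, adjusted p = 0.084), ERBB3 (0.19, 0.483) and BCL2L11 (adjusted p = 0.0827, not above background at 96 h) did not pass. TYR was above background in neither group.

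Respiratory chain genes rose in 23 of 71 cases with none falling (24 adjusted over the list alone), at a median of 0.36 (camera adjusted p = 1.6e-05, and adjusted p = 0.21 with an estimated correlation). CYCS was 2.88-fold higher (SE 0.23). The call was also lost with an estimated correlation for complex I (12 of 34 rising, median 0.32, camera adjusted p = 0.00339, and adjusted p = 0.303), complex IV (6 of 10, median 0.55, 0.00339 and 0.197) and complexes II and III (4 of 12, median 0.46, 0.0114 and 0.092). The same held for antigen presentation, with 10 of 18 rising and 1 falling at a median of 0.72 (camera adjusted p = 0.000431, and adjusted p = 0.197 with an estimated correlation), and for autophagy, with 6 of 21 rising at a median of 0.33 (camera adjusted p = 0.0253, and adjusted p = 0.105 with an estimated correlation; 0.0514 without 96 h replicate 2). ATF4 response genes fell in 9 of 21 cases and rose in 2, at a median of -0.41 (camera adjusted p = 0.0272, and adjusted p = 0.197 with an estimated correlation). SLC7A11 was 9.48-fold lower (SE 0.18) and ATF3 3.1-fold higher (SE 0.18). Secreted factors of senescent cells rose in 10 of 23 cases and fell in 3, at a median of 0.53 (camera adjusted p = 0.0336, and adjusted p = 0.21 with an estimated correlation). The list's median change from 72 h to 96 h was 0.36, and its median difference between the DMSO arrays was 0.21. CXCL8 was 20.7-fold (SE 0.29) and IL6 9.2-fold higher (SE 0.21) and MMP1 7.54-fold lower (SE 0.23). Without 12 h replicate 1 that list's median was 0.287 (adjusted p = 0.051). The CDK inhibitor gene CDKN1C, not above background at 96 h, was at least 3.78-fold lower than at 12 h, CDKN2A was 2.75-fold lower (SE 0.35), and CDKN1A and CDKN1B had log2 fold changes of -0.27 (adjusted p = 0.24) and 0.04 (adjusted p = 0.898; -0.14 with median scaling). With the replicate number as a block in a fit of the 12 treated arrays the count of genes was 5703 (2925 higher and 2778 lower), and with median scaling it was 2856 (1122 and 1734).

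From one time to the next, the number of genes past the threshold was larger in the first 2 steps than in the later ones, but the sizes did not follow that order. Over the 5 steps the median absolute log2 change was 0.25, 0.25, 0.16, 0.16 and 0.27. From 12 h to 24 h 1406 genes differed (769 higher and 637 lower). Of the G2/M genes, 48 of 51 fell (49 adjusted over the list alone) at a median of -2.51 (camera adjusted p = 3.3e-66). TOP2A was at a log2 fold change of -4.45 (SE 0.38) and LMNB1 at -2.49 (SE 0.20). HMOX1 had a log2 fold change of -2.07 (SE 0.22, adjusted p = 4.3e-05). The count was 668 without 24 h replicate 2, 2119 without DMSO replicate 1, between these without the other arrays compared (806 without 12 h replicate 1, 746 without 12 h replicate 2, 768 without 24 h replicate 1). It was 906 with median scaling and 3149 with the replicate block in the treated arrays. From 24 h to 48 h 721 genes differed (300 higher and 421 lower). CRYAB, LGI3 and PMEL were at log2 fold changes of 2.64 (SE 0.25), 2.26 (SE 0.27) and 1.89 (SE 0.24) and SLC7A11 at -2.24 (SE 0.18). G2/M genes had a median of 0.44, with 6 of 51 rising (15 rose and 1 fell adjusted over the list alone; camera adjusted p = 5.38e-08, and adjusted p = 0.0618 with an estimated correlation). That count of genes was 196 to 276 when an array of 24 h or 48 h was left out (265 and 196 without 24 h replicates 1 and 2, 214 and 276 without 48 h replicates 1 and 2). It was 1529 and 1514 without DMSO replicates 1 and 2, 365 with median scaling and 2639 with the replicate block in the treated arrays.

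No gene passed limma's threshold from 48 h to 60 h, with 418 at an unadjusted p under 0.05, and no gene did so from 60 h to 72 h, with 466 unadjusted and 2 with the replicate block in the treated arrays. Interferon-stimulated genes shifted down as a list from 60 h to 72 h, at a median of -0.40 (camera adjusted p = 5.04e-11), although 0 of 25 passed singly and 7 fell adjusted over the list alone. From 72 h to 96 h 6 genes differed, all named after their values were seen. IL32, a cytokine gene, was higher (SE 0.18, limma adjusted p = 0.0444). SCRG1 (log2 fold change -1.76, SE 0.19), MLH3 (-1.57, SE 0.19), TCN1 (-1.42, SE 0.18), CD96 (-1.33, SE 0.18) and CDH19 (-1.23, SE 0.19) were lower. At an unadjusted p under 0.05 there were 2325 genes. In the fit of treated arrays only, which left the fold changes as they were, 991 genes passed limma's adjusted threshold. The count of 6 thus rested on the spread of the DMSO arrays, which are not part of this comparison. The count of genes past the threshold was 1019 and 1009 without DMSO replicates 1 and 2, 3 and 0 without 72 h replicates 1 and 2, 0 without 96 h replicate 2, 828 with array weights and 2308 with the replicate block in the treated arrays. By the F test, genes differing among the 6 PLX4720 times numbered 3575 (2329 and 2368 without 12 h replicates 1 and 2, 7226 with the replicate block in the treated arrays). Among them were LMNB1 (adjusted p = 5.67e-06), MYC (8.9e-06) and PPARGC1A (0.000137), but not CDKN1A (0.473) or CDKN1B (0.544). The signal of CDKN1A lay near the top of the scale, so its result does not show a stable transcript.

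PPARGC1A was higher than in DMSO at each of the 6 times, with log2 fold changes of 0.89, 2.44, 3.15, 2.95, 3.15 and 2.69 at 12, 24, 48, 60, 72 and 96 h, and the respiratory chain list had medians of 0.16, 0.39, 0.36, 0.45, 0.37 and 0.53. That at 12 h was not called by camera, and with an estimated correlation none was (adjusted p = 0.122 to 0.714). PMEL, above background on 1 of the 2 arrays in DMSO and at 24 h, went from 0.34 and 0.02 at 12 h and 24 h to 1.91, 2.87, 3.48 and 4.96, and IL6 from 0.09 at 12 h to 3.29 at 96 h through 0.65, 1.15, 1.77 and 2.11. The interferon list turned, with medians of 0.59, 0.69, 0.32, 0.08, -0.15 and -0.43, those of leukocyte markers being 0.38, 0.31, -0.12, -0.05, 0.06 and 0.37. HMOX1 came down from 3.71 at 12 h to 1.64 at 24 h and 1.31 at 96 h. The measured value of CDKN1A, near the top of the signal scale, lay between -0.30 and -0.60 at each time.

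Between 12 h and 96 h against DMSO, 922 genes were called with the same sign, 401 higher and 521 lower. Independent lists of these sizes would share 188 and 142. Unchanged groups simulated 100 times against a shared, also simulated, DMSO pair had 0.2 shared calls on average. No gene was altered in the simulations, so a low count was set by construction and gives no level for lists of these sizes. Noise was drawn separately for each gene, so a difference between the DMSO arrays common to many genes was not simulated. Across genes, which are not independent replicates, the fold changes correlated with r = 0.37, against 0.724 in the simulations, with a covariance of 0.17 against a simulated 0.0784, a difference of 0.0913. The DMSO pair was too small to be split, so part of the excess may come from the shared controls. The shared count was 336 with array weights, 1428 without DMSO replicate 2, and 595 and 534 without 12 h replicates 1 and 2. In 272 genes the signs were opposite, 153 higher at 12 h and lower at 96 h and 119 the reverse. All 272 were also called between 96 h and 12 h. This adds no support, since 2 called effects of opposite sign differ by more than either effect at the same SE.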

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

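The tests of gene length and of CDKN1A probes below were set before their results were seen, and the other tests of this part were chosen only after the result was seen. The first set of results was picked out because the effect against DMSO differed between 12 h and 96 h, by limma and camera on the difference between the times itself, which also holds hours in culture. In 272 genes the effect was in opposite directions at the 2 times. As lists, the median log2 difference of 96 h from 12 h was 0.68 for ERK output, 0.32 for complex I, 0.46 for complexes II and III, 0.55 for complex IV, 0.36 for all respiratory chain genes, 0.94 for the pigment lineage, 0.53 for secreted factors of senescent cells, 0.65 for lysosome, 0.33 for autophagy and 0.72 for antigen presentation, and it was -1.17 for G1/S, -2.38 for G2/M, -1.03 for interferon-stimulated genes and -0.41 for the ATF4 response. With an estimated correlation 6 of these 14 lists kept the call (ERK output, pigment lineage, G1/S, G2/M, lysosome and interferon), and the other 8 did not pass.

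Among single genes the log2 difference of 96 h from 12 h was -4.40 for ART3, -4.12 for HKDC1, -4.07 for TOP2A, -3.95 for PBK, -3.92 for BUB1, -3.71 for ISG15, -3.56 for TK1, -3.54 for HMMR, -3.25 for SLC7A11 and -1.53 for SESN1. It was 4.90 for ANGPTL7, 4.37 for CXCL8, 3.56 for TYRP1, 2.53 for MAFF, 1.80 for WIPI1, 1.79 for PFKFB2 and 1.28 for NDRG1. Not above background at 96 h, ID1 was at least 15.5-fold, NCAPG at least 13.5-fold and CDCA2 at least 6.23-fold lower than at 12 h. HKDC1, PBK, BUB1, ISG15 and HMMR were above background on 1 of the 2 arrays of 96 h. A signal was also present in probes that the gene comparisons did not use: of 5880 tested probes without a gene name, 363 were higher and 481 lower at 96 h than in DMSO.

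The first pattern weighed is that genes moved from 72 h to 96 h in parallel with the difference between the 2 DMSO arrays, with 79.1% of genes of the same sign. Gene length was taken as genomic span, introns included, and transcript length was not tested. On the log2 scale it correlated at r = -0.25 with the difference between the DMSO arrays and at -0.26 with the step from 72 h to 96 h. A trend along genomic span did not account for the pattern, since r across genes, which are not independent replicates, was 0.693 after its removal. Nor did the replicate number, since the nearest 72 h and 96 h arrays lay 30.1 apart on the axis whichever their number. Brightness was not decided. The DMSO arrays' median raw signals had a ratio of 1.01, but both medians (366 and 370) lay below the limits for a probe above background (411 and 427). They thus say little about the brightness of expressed genes. Hours in culture alone would not set the DMSO arrays apart, since both were labelled 96 h. Whether hours shaped the step from 72 h to 96 h cannot be told from the axis. A share of 0.831 of the within-group spread along it came from the DMSO pair, which lay apart on it by construction. A difference in RNA or labelling between arrays that the labels do not record stays open, with r = 0.719 between the differences, and it may add to late changes in treated cells.

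The second pattern is that G2/M genes were higher at 12 h than in DMSO. A single odd DMSO array did not account for it: the median with 1 DMSO array left out was 0.785 or 1.04. Slower division of the control culture by 96 h could raise the 12 h values equally well, and with 0 control arrays taken at 12 h it cannot be told apart from an early effect of the drug. The fall of the same genes from 12 h to 24 h, at a median of -2.51, was measured between treated arrays.

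The third pattern is that CDKN1A, which encodes p21, was not higher at any time by its only probe above background. Its probe reached a raw signal of 70970, near the largest of any probe, 72790, and its measured value was lower than in DMSO at each time, though higher at 12 h with median scaling (0.134 for CDKN1A). A rise hidden by the top of the scale cannot be told apart from a true lack of one, and the size of a fall is likewise open. A dimmer probe above background would decide it, but there were 0 such probes. The gene's other probe was above background on 0 arrays. Its mean was above that of DMSO at each time, by 0.81 on the log2 scale at 96 h. At background level this gives neither size nor direction.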

How the results depend on the processing

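The mode as background, the array axis, the fit of treated arrays only and its replicate block were chosen after the data were seen; neqc and a block by slide were not run (no detection p-values or slide numbers used here). Named genes with a call kept direction and call in 3939 cases under alternatives and in 4052 with 1 array left out, were lost in 290 and 324, and never reversed; called lists kept both in 579 and 539, were lost in 47 and 21, and turned in 2 and 0. A case is 1 gene or list under 1 setting, so these counts do not give the share of genes that kept their call throughout. By gene, array weights ended 38 of 91 named calls at 12 h against DMSO. They ended 30 of 111 at 96 h against DMSO and 0 of 111 for 96 h against 12 h. Median scaling ended 24, 23 and 16. Named calls kept under every setting tried, those with 1 array left out included, were 46 of 91, 69 of 111 and 81 of 111 in the same order. Many of these genes were named for the size of their change in these data, so a turned direction was unlikely. Array weights and the fit of treated arrays only left the fold changes as they were, so counts moved through the spread. For other settings, where the cause is not given by fewer arrays or genes, the cause was not tested. A group left with 1 array was assumed to vary like the others. Signal over background limits genes that are dim in a group to bounds, and genes above it in neither group were not followed.

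Counts of genes against DMSO at 12, 24, 48, 60, 72 and 96 h were 854, 1197, 1529, 1609, 1930 and 1896 with array weights, 870, 1301, 1592, 1690, 2042 and 2324 with only the groups compared (fewer arrays), and 3479 and 4013 at 12 and 24 h with the axis as covariate. With 1 array left out they were 1128 to 2849, 1241 to 3179, 1946 to 4299, 1938 to 3698, 2058 to 4478 and 2521 to 4733. Left out likewise, 96 h against 12 h gave 2467 to 4582, 24 h against 12 h 668 to 2119, 48 h against 24 h 196 to 1529, 60 h against 48 h and 72 h against 60 h 0 to 0, 96 h against 72 h 0 to 1019, the F test 2329 to 5289 and shared calls 534 to 1428. From 12 h to 24 h the count was 906 with median scaling, 908 without a filter on dim probes, 2276 with array weights and 2401 with the axis. From 24 h to 48 h it was 365, 344 and 1594 with the first 3 of these, and 1480 with treated arrays only. From 72 h to 96 h it was 18 with deposited values, 16 without background correction, 14 with an offset of 50, 12 with trended variance, 1 with median scaling and 1 without the filter, 2 with the mean of probes and 2 with the axis, 0 with only the groups compared, 828 with array weights and 991 with treated arrays only. The F test gave 2334 with median scaling. Shared calls were 603 without the filter, 336 with array weights, 393 with only the groups compared and 1475 with the axis.

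With the replicate block the count was 1172 from 24 h to 48 h and 24 from 72 h to 96 h, and CDK inhibitors and senescence had -0.334 (adjusted p = 0.0558 by limma's camera). With the block among treated arrays the counts were 5703 for 96 h against 12 h, 3149 and 2639 for 24 h and 48 h against the time before, 2 from 60 h to 72 h, 2308 from 72 h to 96 h and 7226 by the F test. Lists called for 96 h against 12 h were then 15, and 16 with the block in all arrays. Among named genes the block ended 2 calls, those of the TFAM log2 fold change, 12 h against DMSO (adjusted p = 0.0518), and the SUCLG2 log2 fold change, 96 h against DMSO (0.0522). It added the MITF log2 fold change, 96 h against DMSO (0.0344), and, among treated arrays, the TFAM log2 fold change, 96 h against 12 h (0.00342), and the BCL2L11 log2 fold change, 96 h against 12 h (0.0356). It moved no other count by over 1.5 times and changed no other call of a named gene.

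Lists called by fry were 16 at 12 h, 31 at 96 h and 29 for 96 h against 12 h, with glycolysis (0.299) and secreted factors (0.674) called at 96 h, and 7 and 6 in the last 2 with an estimated correlation, which lost the respiratory chain (0.53) and CDK inhibitors and senescence (-0.334) at 96 h. Lists called with 1 array left out were 6 to 10, 16 to 19 and 13 to 15. Medians at 96 h then were -1.381 to -1.002 for ERK output, 0.398 to 0.582 for the respiratory chain, 0.179 to 0.472 for glycolysis, 0.826 to 1.08 for pigment lineage, -1.048 to -0.976 for G1/S, -1.62 to -1.451 for G2/M, -0.387 to -0.145 for CDK inhibitors and senescence and 0.401 to 0.707 for secreted factors. The call of CDK inhibitors and senescence was also lost with deposited values (-0.145), without background correction (-0.17), with median scaling (-0.466), with an offset of 50 (-0.279) and with probes above background on all arrays (-0.182).

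Directions turned at 96 h against DMSO with median scaling for complex V (-0.125), mitochondrial biogenesis (-0.306), mitoribosome (-0.254), BCL2 family (-0.101), hypoxia (-0.305), ribosome biogenesis (-0.348), TFAM (-0.221) and SLC2A1 (-0.293), and with the axis for mitochondrial biogenesis (-0.025), ribosome biogenesis (-0.011), fibroblast markers (0.018) and SLC2A1 (-0.034). So did p53 targets (0.069) and ERBB3 (0.374) with the mean of probes, interferon (0.056) and fibroblast markers (0.071) with probes above background on all arrays, leukocyte (-0.03) and keratinocyte markers (0.02) without the filter and ERBB3 with deposited values (0). At 12 h MITF (0.094) and ERBB3 (0.173) turned with the mean of probes and CDKN1A (0.134) and AXL (-0.084) with median scaling, and CDKN1B did for 96 h against 12 h (-0.14). With 1 array left out, values at 96 h against DMSO that turned ranged from -0.011 to 0.102 for mitochondrial biogenesis, -0.173 to 0.028 for receptor tyrosine kinases, -0.102 to 0.126 for p53 targets, -0.156 to 0.052 for heat shock, -0.122 to 0.108 for ribosome biogenesis, -0.156 to 0.077 for fibroblast markers and -0.048 to 0.27 for endothelial markers. The median log2 fold change of the list reference genes, 96 h against DMSO, was then -0.351 to 0.08. They ranged from -0.327 to 0.726 for TFAM, -0.169 to 0.472 for SLC2A1 and -0.02 to 0.017 for ERBB3. The MITF log2 fold change, 12 h against DMSO, was -0.754 to 0.227 and that of CDKN2A -0.509 to 0.186. The CDKN1B log2 fold change, 96 h against 12 h, was -0.181 to 0.269.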

Other observations

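The hypotheses on NRF2 and BMP targets below were set out before their tests were run, after HMOX1, GCLM, ID1 and ID3 had been seen among the largest rises at 12 h. HMOX1, GCLM and AKR1B10 are targets of NRF2, the transcription factor of the oxidative stress response. Of 13 other NRF2 targets 7 rose at 12 h against DMSO, none fell and 6 did not pass, at a median of 0.62 (limma's camera, p = 3.42e-06 for this single list, and 0.00172 with an estimated correlation), so the hypothesis of a shared NRF2 response passed its test. The only control was taken at 96 h, so the drug and hours in culture cannot be told apart in this rise or in the later fall. The thioredoxin reductase gene TXNRD1 was 5.05-fold higher, the sulfiredoxin gene SRXN1 4.15-fold and the glutathione reductase gene GSR 2.15-fold. At 96 h the list's median was -0.04, with 3 rising and 2 falling. Between 96 h and 12 h 9 of the 13 fell and none rose, at a median of -0.88. The list's median was thus no longer above DMSO at 96 h, while TXNRD1 (1.61-fold), SRXN1 (1.43-fold) and TALDO1 (1.42-fold) still were.

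ID1 and ID3 are targets of BMP signalling through SMAD proteins. Of 7 other targets 4 rose at 12 h and 2 fell, at a median of 0.65. By limma's camera the p for this single list was 0.152, so the hypothesis of a shared BMP response was not borne out. ID2 was 3.82-fold and the inhibitory SMAD6 3.46-fold higher, whereas HEY1 had a log2 fold change of -1.29.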
